A study of Prunus persica with 2 samples.

How the data were processed

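RNA was sequenced from wound tissue of peach (Prunus persica) fruit. Per the labels, wounds had received 30 μL of either sterile water or a suspension of the yeast Pichia membranaefaciens, fruit were held at 28 °C and 95% relative humidity, and tissue was taken on day 3. There are 2 libraries, 1 per treatment, and each was assigned to its group from its treatment label. Per the labels' protocols, RNA was extracted with a column and Trizol kit and libraries followed standard Illumina procedures; whether the kit kept strand is not given in the sources used here.

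HISAT2 (a spliced read aligner) and HTSeq 0.6.1 (a read counter) are named in the submitters' processing notes, with no role or order. The genome build, the annotation and the program that assembled transcripts are not given in the sources used here. The FPKM values (fragment numbers scaled for exon length and for library depth) were deposited by the authors in 1 gene table with 27806 rows and in 1 transcript table per library with 51199 rows. Of the gene rows, 26873 carry identifiers of annotated genes and 933 carry identifiers of loci assembled anew from the reads. The transcript tables also hold coverage, deposited by the authors as the mean number of reads over each base of a transcript. The positions below are those of the transcript tables, counted from 1, on pseudomolecules Pp01 to Pp08 and on unplaced scaffolds.

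How the gene values were made was tested on the files. In 96.2% of the 15475 rows above 0.5 FPKM in both libraries, the gene value equalled the sum of transcript FPKM times transcript length, divided by a whole number of bases that was the same in both libraries (tolerance 0.01 bases and a relative difference of 0.0001). In these rows the gene value therefore adds the reads of the transcripts over 1 fixed length per gene, and is not a whole read count. Among the rows analysed, 604 share their pair of values with at least 1 other row, in 284 sets, and 271 of these sets lie in 1 merged locus each. Such rows are not separate measurements.

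Neither the gene table nor the transcript tables pair identifiers with gene names or products. None of the identifiers (0) matched a field of the RefSeq gene table for the Prunus_persica_NCBIv2 assembly. Lists of defence, hormone, ripening and tissue marker genes had been fixed by product name before the data were examined, and could not be applied by name. The rules fixed beforehand also allowed some lists to be matched on translated coding sequences. No such match was made here. By the rule fixed for this case, the text names the 2 identifiers with the largest and the 2 with the smallest difference. Other loci are given by position, and were chosen after their values were seen.

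Depth was read from the transcript tables. Coverage divided by FPKM was 8.04 in every control transcript above 1 FPKM and 7.54 in every treated one, which corresponds to 8.04 and 7.54 gigabases of fragments. The product of coverage and length over barely covered transcripts was most often 300 bases, then 600 and 900, in each library. Taking 300 bases as 1 fragment gave about 26800000 fragments for the control library and 25100000 for the treated one. A gene of the median annotated length (1612 bases) at 1 FPKM in the control library then rests on about 43.2 fragments (95% Poisson interval 31.1 to 57.9). Fragment numbers are estimates from the authors' division of reads among transcripts, and their intervals cover counting error only.

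The comparison was the difference of log2(FPKM + 1), treated minus control, with a pseudocount of 1. A gene entered when it reached 1 FPKM in at least 1 library, and counted as higher or lower when the difference was 1 or more in size. On this scale the change of low genes is understated. With 1 library per group there is no replicate error, so no test, p-value or mean ± SD is given. Intervals of ratios are exact (Clopper-Pearson) at 95% from the fragment numbers. Runs of neighbouring genes were counted over annotated genes on the pseudomolecules, each with the FPKM sum of its own annotated transcripts, leaving out those under 1 FPKM in both libraries, and set against 10000 shuffles of the calls over the gene order, as a description of these libraries. The lower share expected from transcript length was averaged over length deciles, with an interval from 1000 bootstrap draws of called genes. Transcript shares were computed for genes with at least 5 FPKM in both libraries.

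The calling rule was tested on simulated counts for 15197 genes with the depths above and 200 genes changed. Among changed genes at 5 FPKM or more, it called 36 of 36 that were made 4-fold higher and 34 of 34 made 4-fold lower. It called none (0) of 33 made 1.5-fold higher and none (0) of 30 made 1.5-fold lower. At 5 FPKM or more, the threshold largely sets both the 4-fold and the 1.5-fold results in advance. Of 14997 unchanged genes, 1 was called. The simulation held counting error and no difference between fruit. Alternatives changed the pseudocount (0.1 or 5), the filter (none, or 5 FPKM), the scaling (upper quartile, trimmed mean, or an equal sum over all genes), the source of gene values (transcript sums), the newly assembled loci (left out) and the threshold (2). After the data were seen, counts with identical rows taken once, and counts without new loci opposite another transcript, were added. A transcript counted as opposite when it overlapped the locus and its listed strand differed, also where either had no strand listed. Work was done in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.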

Results

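The transcriptome of wounded peach fruit was profiled in 2 libraries, 1 from wounds given sterile water and 1 from wounds given Pichia membranaefaciens, a yeast studied as a biological control agent against postharvest rot. Both were sampled 3 days after treatment, and there were no replicates. The question stated for the series was which genes related to resistance differ in expression between tissue treated with the yeast and tissue without it. The control library held about 26800000 fragments and the treated library about 25100000. At least 1 FPKM was reached by 14637 gene rows in the control library and by 14738 in the treated library.

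The transcript profile of the wound was largely alike with and without the yeast. Of 15197 genes measured, 14695 (96.7%) differed by less than 1 on the log2(FPKM + 1) scale, and 13191 (86.8%) by less than 0.5. The treated library was higher by 1 or more at 244 genes (1.61%) and lower at 258 (1.70%). A difference of 2 or more was seen at 40 higher and 53 lower genes. The median difference was 0.02, and the central 90% of genes lay between -0.57 and 0.58. Across genes, which are not independent replicates, Pearson's r of the log2 values was 0.97. The genes past the rule had a median of 349 fragments in the library where they were more abundant, and 41 of the 502 had fewer than 30. These are fragments of the transcripts assigned to each row. For a row with the value of a merged locus, they can differ from the fragments behind that value. Without replicate fruit, the difference between treatments cannot be set against the difference between samples of the same treatment.

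**Figure D1:**
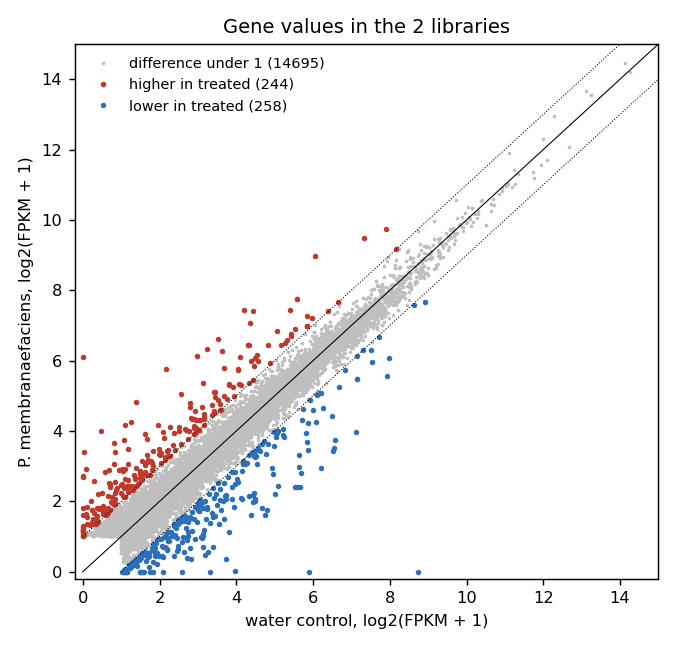
Each point is 1 of 15197 genes, placed by log2(FPKM + 1) in the water control library (x axis) and in the P. membranaefaciens library (y axis); the solid line marks equal values and the dotted lines a difference of 1. Red points are the 244 genes higher and blue points the 258 genes lower in the treated library, and the 14695 grey points fill the band between the dotted lines.

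The most abundant genes were largely the same in both libraries. The 10 most abundant genes took 14.5% of all FPKM in the control library and 16.2% in the treated library, and 9 of the 10 were the same genes. None of the 44 genes with a mean of 1000 FPKM or more passed the rule, with differences between -0.66 and 0.84. Among 882 gene rows with a mean from 100 to 1000 FPKM, 11 were higher, with 10 distinct pairs of values because 2 rows share a merged one, and 10 lower. Below a mean of 5 FPKM, 4.95% of 4966 genes passed it, compared with 2.23% of 3811 genes between 20 and 100 FPKM. Among annotated genes with a mean of 100 FPKM or more in the gene table, the largest difference upward was at a gene of 3 exons on the minus strand of Pp03, 957511 to 958712, with 65.7 FPKM in the control and 501 FPKM in the treated library. A gene of 3 exons on Pp05, 9816076 to 9818049, had 161 FPKM in the control and 721 FPKM in the treated library. In the other direction, a gene of 5 exons on Pp07, 21459369 to 21461207, had 240.2 FPKM in the control and 46.1 FPKM in the treated library. A further gene of 5 exons on Pp05, 8722019 to 8725271, had 249.5 and 66.0 FPKM.

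By the fixed rule, the 2 identifiers with the largest upward difference were MSTRG.708 and Prupe.8G024800. The annotated gene Prupe.8G024800, with 3 exons on the plus strand of Pp08 from 2253080 to 2255075, had 3.50 FPKM in the control and 53.5 FPKM in the treated library, a difference of 3.60. It rested on about 78 and 1122 fragments, a ratio of 15.3 with a counting interval of 12.2 to 19.6. A pair of unannotated transcripts on the opposite strand inside it summed to 0.453 FPKM in the control and 17.6 FPKM in the treated library. MSTRG.708, an unannotated locus of 2 exons on the minus strand of Pp01 from 10046424 to 10046828, was listed at 0 in the control and at 68.2 FPKM in the treated library. It lies inside an annotated gene on the opposite strand that had 4932 FPKM in the control and 7998 FPKM in the treated library. The 2 identifiers with the largest downward difference, MSTRG.12725 and MSTRG.4779, were also unannotated and opposite another transcript. MSTRG.12725, a single exon on the plus strand of Pp07 from 4020 to 5834, had 427 FPKM in the control and was listed at 0 in the treated library. The transcript over the same bases of the minus strand had 427 and 363 FPKM. MSTRG.4779, a single exon on the minus strand of Pp02 from 24127296 to 24128451, had 58.4 FPKM in the control and was listed at 0 in the treated library, beside a plus-strand transcript of the same span with 523 and 595 FPKM. No source used here states whether strand was kept, and strandedness was not tested, so it is not known whether reads from the strands of such a pair were separated. In all, 5 loci stood at 0 in one library and at 5 FPKM or more in the other. Each was a newly assembled locus, with a strand listed, within the span of a transcript counted as opposite. That count takes any listed strand other than that of the locus, and would include a transcript with no strand listed.

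Neighbouring genes on Pp01 were higher together in the yeast-treated wound. All 7 annotated genes between 9985573 and 10015956, a span of 30.4 kb, passed the rule, and each has 2 exons; 5 lie on the plus strand and 2 on the minus strand. Their summed value was 118 FPKM in the control and 515 FPKM in the treated library, and the differences of single members ran from 1.05 to 2.25. The most abundant member, at 10010102 to 10011080, had 59.99 FPKM in the control and 286 FPKM in the treated library, a ratio of 4.77 (counting interval 4.50 to 5.06). The least abundant, at 9997626 to 9998505, had 0.588 and 2.28 FPKM, a ratio of 3.82 with a counting interval of 1.98 to 7.96. Of 12 annotated genes in the next 45 kb, 8 were above their control value, 2 below it and 2 at 0 in both libraries, and 2 of the 8 passed the rule. That stretch holds the gene at 10046006 to 10047060 with 4932 and 7998 FPKM, a difference of 0.70.

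**Figure D2:**
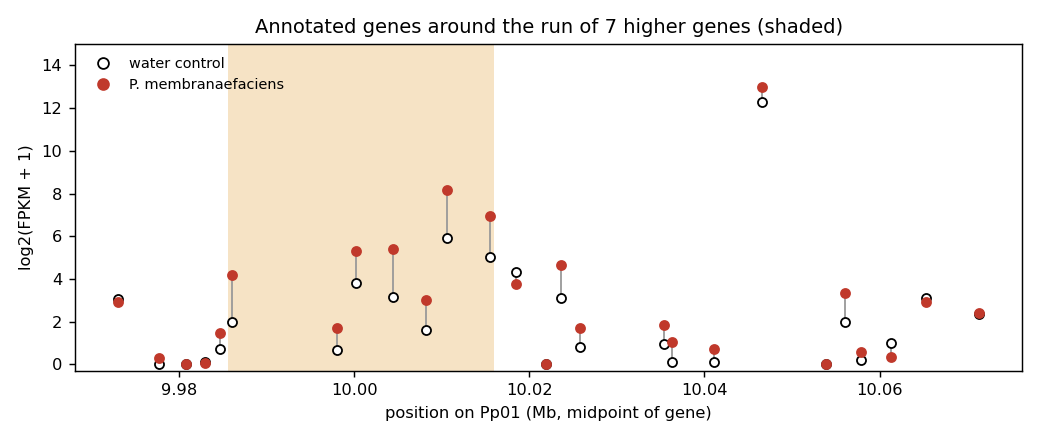
Annotated genes on Pp01 from 20 kb before to 60 kb after the run, each drawn at its midpoint (x axis, Mb) with its log2(FPKM + 1) (y axis) in the water control (open circles) and in the P. membranaefaciens library (red circles). In the shaded run all 7 genes lie higher in the treated library, by 1.05 to 2.25.

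Shorter groups of neighbours differed in the same way elsewhere, where neighbours are next to each other among genes that reached 1 FPKM. A run of 3 higher genes lay on Pp04 from 9619422 to 9641308, with summed values of 32.5 FPKM in the control and 107 FPKM in the treated library; 2 annotated genes under 1 FPKM within it were passed over. Another run of 3 lay on Pp08 from 9364275 to 9476555, with 18.7 and 48.1 FPKM and 1 such gene passed over. There were also 3 adjacent pairs in which both genes differed by 2 or more, 1 of them on an unplaced scaffold and so outside the counts of runs and pairs on the pseudomolecules. On Pp01 from 312661 to 321560, 1 member had 17.5 and 172 FPKM and the other 6.93 and 69.0 FPKM. On scaffold_71 from 12 to 10574, 1 member had 1.60 and 27.5 FPKM and the other 8.35 and 80.2 FPKM. On Pp02 from 25578221 to 25588594, a pair of single-exon genes was lower, with 1 gene under 1 FPKM between them, and with 46.5 and 4.31 FPKM at 1 member and 44.9 and 4.33 FPKM at the other. Members of such groups that are near-identical copies can share reads, which leaves their single values uncertain. With annotated transcripts alone, 305 of 13335 genes on the pseudomolecules were higher and 311 lower. By the gene values, fewer annotated genes passed, 207 higher and 226 lower of 14268. Leaving out newly assembled transcripts can move a gene past the rule where reads were assigned to such a transcript in 1 library. How far this adds to the calls, and to the adjacent pairs below, was not tested. The higher genes formed 27 adjacent pairs, against a median of 7 and a maximum of 17 over 10000 shuffled orders, and 3 runs of 3 or more, a number reached in 3 of the shuffled orders. The 27 pairs include those inside the 3 runs, among them the run of 7 on Pp01, so pairs and runs are not separate counts. The lower genes formed 15 adjacent pairs, against a median of 7 and a maximum of 18; 46 of the 10000 shuffled orders held as many. They formed no run of 3.

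Genes that were higher and genes that were lower differed in exon number. Among annotated genes with 2 to 3 exons, 91 of 3096 were higher and 42 lower. Among those with 10 or more exons, 12 of 3419 were higher and 68 lower, so that 85.0% of the genes past the rule were lower (exact 95% interval 75.3% to 92.0%, over genes). This share goes with few higher genes, 0.35% of the class compared with 2.94% at 2 to 3 exons. The lower genes were 1.99% of the class, compared with 2.61% at 1 exon, 1.36% at 2 to 3 and 1.30% at 4 to 9. Below a mean of 5 FPKM they were 4.96% of the class, compared with 1.99%, 1.84% and 2.29% in the same order. At 5 to 20 FPKM they were 1.51%, and from 20 FPKM 0.77%. Both lay below single-exon genes (2.89% and 3.50%) and slightly above the other classes. Single-exon genes were more evenly divided, with 46 higher and 38 lower of 1455, as were genes of 4 to 9 exons, with 54 higher and 78 lower of 5988. The class of 10 or more exons as a whole was not lower: its median difference was 0.05. At a difference of 2 the same class held 1 higher and 7 lower genes. These counts take merged genes with identical values once.

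**Figure D3:**
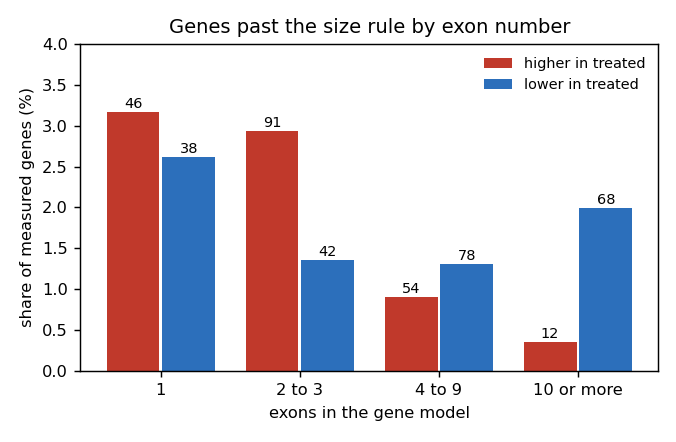
Share of measured annotated genes (y axis, percent) that were higher (red) or lower (blue) by 1 or more in the treated library, by the exon number of the gene model (x axis); the numbers over the bars are genes. Higher genes outnumber lower ones at 2 to 3 exons (91 and 42), and lower genes outnumber higher ones at 10 or more exons (68 and 12).

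Some genes with nearly equal totals had different leading transcripts in the control and the treated library. Of 5620 genes with at least 2 transcripts and 5 FPKM in both libraries, 714 (12.7%) had another leading transcript in the treated library. The total of the gene differed by 1 or more in 63 (1.12%). The share of a transcript moved by 50 percentage points or more in 221 genes (3.93%). In 216 of these the total differed by less than 1, and in 5 by 1 or more. The 221 genes had a median total of 11.7 FPKM in the control library, below the examples that follow. Their median number of transcripts was 4, compared with 3 over all. A gene on Pp01 from 27492946 to 27498224 had a total of 76.6 FPKM in the control and 78.4 FPKM in the treated library. Its transcript of 5 exons made up nearly the whole total in the control and 3.03% of it in the treated library, where a transcript of 6 exons made up 95.5%. A second gene on Pp01, from 28592036 to 28595021, had totals of 126 and 125 FPKM. There a transcript of 1 exon held 89.7% of the total in the control and 3.54% in the treated library, and the remainder was a transcript of 2 exons. These shares are the authors' estimates from short reads, and how far they vary between libraries of the same treatment is unknown.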

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

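The counts of 244 higher and 258 lower genes depended most on the pseudocount and the threshold. With a pseudocount of 0.1 there were 491 higher and 447 lower genes, with a pseudocount of 5 there were 87 and 87, and at a difference of 2 there were 40 and 53. With a filter of 5 FPKM, 164 lower genes were left of the 258, and 163 higher ones. Fewer low genes enter or pass under the higher pseudocount, threshold and filter by construction. The counts stayed within 1.5 times of the main ones under upper quartile scaling (237 and 264), trimmed mean scaling (236 and 262), rescaling to an equal, larger sum over all genes (353 and 346), transcript sums (256 and 282) and without new loci (207 and 226). They did so as well under 2 alternatives chosen after seeing the data, identical rows taken once (239 and 257) and no new loci opposite another transcript (227 and 241). Removing the filter (244 and 258) could not change them, because a difference of 1 with a pseudocount of 1 needs at least 1 FPKM in one library. Of the 4 named identifiers, 3 stand at 0 in one library, so no alternative could turn their direction, and Prupe.8G024800 kept its own; 10 of their 33 alternative values moved beyond counting error, all under another pseudocount or the rescaling. The lists of genes by product name, with their matched and unmatched random lists, were not run, because the identifiers matched no names and no match on coding sequences was made. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Of the 502 genes past the rule, 41 had transcripts with fewer than 30 fragments assigned in the library where they were more abundant.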

Other observations

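Newly assembled loci are given apart from annotated genes, with no test and no matching for abundance or length. Of 929 new loci measured, 37 (3.98%) were higher and 32 (3.44%) lower in the yeast-treated wound, and of 14268 annotated genes 207 (1.45%) were higher and 226 (1.58%) lower. Among the 245 new loci opposite another transcript, 17 (6.94%) were higher and 17 (6.94%) lower. Among the 684 others, 20 (2.92%) were higher and 15 (2.19%) lower. The class called opposite can also hold overlaps in which the locus or the transcript has no strand listed. Genes past the rule lay on all 8 pseudomolecules. Annotated genes of Pp08 were higher at 26 of 1368 (1.90%) and lower at 20, and those of Pp05 were higher at 15 of 1342 (1.12%) and lower at 30 (2.24%).

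The length, fragment number, opposite-strand, merged value and shared ratio tests below were chosen with the values already in view, or knowing part of them; the transcript sum and shuffle tests were written down before their results were seen. The length, fragment number and opposite-strand tests each replaced a first form that could not decide. Genes of 10 or more exons were lower 68 times and higher 12 times. A trend with transcript length was argued against as the whole cause. Called genes of fewer exons in the same length deciles would give 44.5% lower (bootstrap interval 34.2% to 55.6%), compared with 85.0% (75.3% to 92.0%). Subtracting the median of each length decile, the first form, worked toward more lower calls in long genes, since the median rose from -0.05 in the shortest decile to 0.14 in the longest. Counting error was argued against, since among called genes of this class with at least 30 fragments in both libraries 61 were lower and 9 higher (exact interval of the lower share 76.99% to 93.9%), where counting error would give equal numbers. Transcript sums (68 of the 68 stayed lower) do not test division of reads among the transcripts of a gene, since the gene values of 67 of them add reads over transcripts. An effect of the treatment, a difference between the sampled fruit and a different mix of cells in the wound stay open and cannot be told apart with 1 library per group.

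The loci with a 0 in one library may reflect how reads were divided between overlapping transcripts. On Pp05, from 15080110 to 15081033, the locus had 8.997 FPKM in the control and was listed at 0 in the treated library. The transcript over the same bases of the other strand went the other way, from 8.66 to 15.1 FPKM, a difference of 0.73 against at most 0.58 in either direction for the central 90% of genes, as division of reads would have it; a real exchange between strands in 1 locus is not excluded. For the loci on Pp01 and Pp02 the question stays open, since at 3 of 3 the reads of the locus were too few beside the opposite transcripts to move these beyond that range. On Pp07 the sum went from 854 to 363 FPKM, a difference of -1.23. The nearly equal control values of that pair, 427.13 and 427.14 FPKM, leave open whether the same reads were counted on both strands, so this locus cannot be told apart from a real decrease. No biological explanation was tested for these loci.

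The run on Pp01 is a candidate for a local group of genes that respond together, a hypothesis found and described on the same libraries. Chance placement over all measured genes alike was argued against, since 0 of 10000 shuffled orders held a run as long. The shuffles did not keep exon number or gene copies in place. All 7 members have 2 exons, and higher genes were 2.94% of genes with 2 to 3 exons and 0.35% of those with 10 or more. The run of 7 was found on the annotated transcripts of each gene alone, so merged gene values did not enter it, and all 7 members have different values. Counting it there is therefore no separate test of merging. By the gene values, the members at 10010102 to 10011080 and 10014969 to 10015956 share 1 merged pair, 47.3 FPKM in the control and 212.8 FPKM in the treated library. Sharing of reads between near-identical copies stays open. The ratios of members ran from 3.00 to 5.84 with counting intervals that did not all overlap. Within counting error, this argues only against 1 pool of reads shared by all 7 members. Some members had overlapping intervals, such as 5.22 (4.43 to 6.18) and 4.77 (4.50 to 5.06). Sharing among some members, or in part, could not be tested without sequence. Whether the yeast or the particular fruit accounts for the run was not tested.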
